A study of Sus scrofa with 6 samples.

How the data were processed

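RNA from abdominal aorta of miniature swine was measured by RNA sequencing in 6 pools, 3 from a group with atherosclerotic lesions and 3 from a lesion-free group. Per the labels, RNA of 11 animals per group was combined into the 3 pools of that group. The labels do not say which animals went into which pool, so a pool is the unit of replication here. The p-values therefore measure the spread between pools, which need not equal the spread between animals. Per the labels' protocols, RNA was extracted with a column kit from powdered tissue and libraries were made with a stranded total RNA kit. Depletion of ribosomal RNA, sequencing instrument, read length, aligner and genome build are not given in the sources used here.

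The authors deposited a table of genes and a table of isoforms, each with 1 column of raw estimated read counts per pool. Per the submitters' processing notes, RSEM 1.3.0 and edgeR were used, without a stated role for either. Every deposited value was a whole number, and values of 1000 and more carried a comma between groups of digits, which was removed. The gene table held 22861 genes, of which 14918 had a count in at least 1 pool. The isoform table held 27927 isoforms. Because RSEM shares reads among isoforms and similar genes by estimation, the deposited counts of near-identical genes or of isoforms of 1 gene are uncertain. The recorded data do not show that uncertainty.

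The commas kept the columns from being recorded as plain counts, and negative binomial count models were therefore set aside. This was a matter of recording only. With the commas removed the values were whole numbers, to which such models could have been applied. The planned main test was the edgeR quasi-likelihood test, which was not run. It was replaced by limma 3.58.1 in R 4.3.3, with voom precision weights and robust empirical Bayes moderation, on log2 CPM (counts divided by library size and scaled to a common base) computed from the deposited counts. The choice of limma was made before any result was seen. Genes were tested when they reached the CPM of 10 counts in a library of median size, here 1.00 CPM, in at least 3 pools, with at least 15 counts in all. This left 11673 genes. Libraries were scaled by the trimmed mean of M values (TMM, trimming 30% of M and 5% of A), and voom added 0.5 to each count before the log. Printed CPM values are counts divided by the TMM-scaled library, except those of RNA classes and immunoglobulin genes as a class, which are divided by the plain library total. A positive log2 fold is higher in lesion pools. All p-values are two-sided and were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. A gene past it is called changed.

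Total counts per pool ran from 4650176 in lesion replicate 1 to 11442433 in lesion replicate 3. A floor of 3 counts equals 0.577 CPM in lesion replicate 1 and between 0.268 and 0.36 CPM in the other pools. Such floors cover counting error only. Replicates were compared before averaging. The chi-square per degree of freedom between pools of 1 group lay between 23.7 and 105, so no pool repeated another within sampling noise.

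Before the data were examined, 42 gene lists, the rule for naming genes and a set of alternatives were fixed. Of these, 25 covered processes and cell types of the diseased artery and 17 served as checks for other cell types, sample handling, body position, sex and RNA quality. They held 833 distinct genes, of which 705 were matched, 608 by the symbol in the table, 91 by the identifier in a reference table of names and 6 by a synonym, and 551 were tested. In the gene table, 7481 genes carried only an identifier, and 1723 of them were named from the reference. Of all identifiers, 50.1% were in that reference. The 34 lists with at least 5 tested members went through limma's camera test with a preset inter-gene correlation of 0.01, adjusted over the lists. The number of called members was also taken with p-values adjusted over the list alone. Alternatives were camera with an estimated correlation and fry, a rotation test of whether the genes of a list move one way.

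The rule for naming genes took ITGB2, named in the series title. It added the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and groups that did not overlap. From each list it took up to 3 called members with the smallest p in the direction most took and 1 in the other direction. For isoform use it took genes with the smallest adjusted p. Genes named outside the rule are said to be so.

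Isoforms were tested as genes were, on 12666 isoforms. Isoform use, that is, whether the isoforms of a gene change unequally, was tested with limma's diffSplice and Simes-combined p-values in 611 genes with at least 2 tested isoforms. An isoform was tied to a gene only where its name without the isoform number was the symbol of a single gene and the isoform counts summed to that gene's count within 1 count per isoform.

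The procedures were tested on simulated counts with the means and library sizes of the real pools and a pool-to-pool spread drawn around the trend of the real one. For the gene comparison, 50 genes were changed at each of 4 sizes among 11289 genes tested. With a 4-fold change 23 of 50 were called, with an 8-fold change 43, with a 2-fold change 3 and with a 1.5-fold change 0. Of the 75 calls, 6 were genes simulated as unchanged. For the list comparison, run on 11276 genes drawn independently of each other, 5 of 5 raised lists and 0 of 35 unchanged lists were called. For isoform use, 42 of 60 genes with 1 isoform raised 8-fold were called among 582 genes tested, beside 1 of 524 unchanged genes, and 0 of 60 among 579 genes with a 2-fold rise.

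The alternatives fixed with the lists were other scaling factors, other low-count filters, sample quality weights, moderation without the robust option, removal of the mitochondrial and 20 most abundant genes, other set tests and leaving out each pool in turn. The limma-trend fit, thinning of every pool to the smallest total, and a fit of protein-coding genes only were added after the data had been seen. No reference genome was used, so GC content was not examined and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.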

Results

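The series compared abdominal aorta of Wisconsin Miniature Swine with familial hypercholesterolaemia (FH), an inherited excess of blood cholesterol, that carried atherosclerotic lesions, with lesion-free aorta of normal swine of the same breed. Its title names ITGB2, the beta-2 integrin chain of leukocytes, as a central gene of early fibro-atheroma. Lesion status and swine line went together in every pool, so each difference below is a difference of both. The labels do not give sex, age, diet or sequencing batch per pool, so differences in these cannot be told apart here either. The 3 lesion pools held 4650176, 10055160 and 11442433 counts (replicates 1, 2 and 3), and the 3 lesion-free pools held 10826175, 8492673 and 9900513 (replicates 4, 5 and 6). Genes with a count numbered 10754 in lesion replicate 1 and 11834 to 13502 in the other pools. On log2 CPM, lesion replicate 1 correlated at 0.79 across genes with each of the other lesion pools, which correlated at 0.91 with each other. The lesion-free pools correlated at 0.83 to 0.89 with each other and at 0.82 to 0.89 with lesion replicates 2 and 3. Lesion-free replicate 6 correlated at 0.893 with lesion replicate 2, above its 0.875 and 0.887 with its own group.

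The main question was which genes differ between lesion and lesion-free aorta. Some genes of macrophages, lipid handling, antigen presentation and complement rose in the lesion pools, and a small set of genes that includes 2 contractile smooth muscle genes fell. ITGB2 was 11.6-fold higher, at 189 ± 57.5 CPM in lesion pools against 16.1 ± 4.3 CPM in lesion-free pools (SD, n = 3 each). APOE, the lipoprotein component that macrophages secrete when they take up cholesterol, was 54.4-fold higher, at 3427 ± 1349.7 against 62.2 ± 23.3 CPM. CNN1, the smooth muscle protein calponin, was 2.57-fold lower, at 3659 ± 687 against 9278 ± 417 CPM.

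Of 11673 genes tested with limma, 113 were higher and 9 lower in lesion pools, and in all 122 the groups did not overlap. Among all genes tested, the groups did not overlap in 19.4%, where chance gives 10%. The log2 fold of ITGB2 was 3.53 (SE 0.38, limma adjusted p = 0.000169), and that of APOE was 5.77 (SE 0.35, limma adjusted p = 7.94e-07). With sample quality weights 213 were higher and 40 lower, and without a low-count filter 171 and 17. The number of higher genes was 65 without lesion-free replicate 5 and 55 without lesion-free replicate 6. The number of lower genes was 5 without lesion replicate 1, 36 without lesion replicate 3, 21 without lesion-free replicate 4, and 4 without lesion-free replicate 5 or 6.

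**Figure D1:**
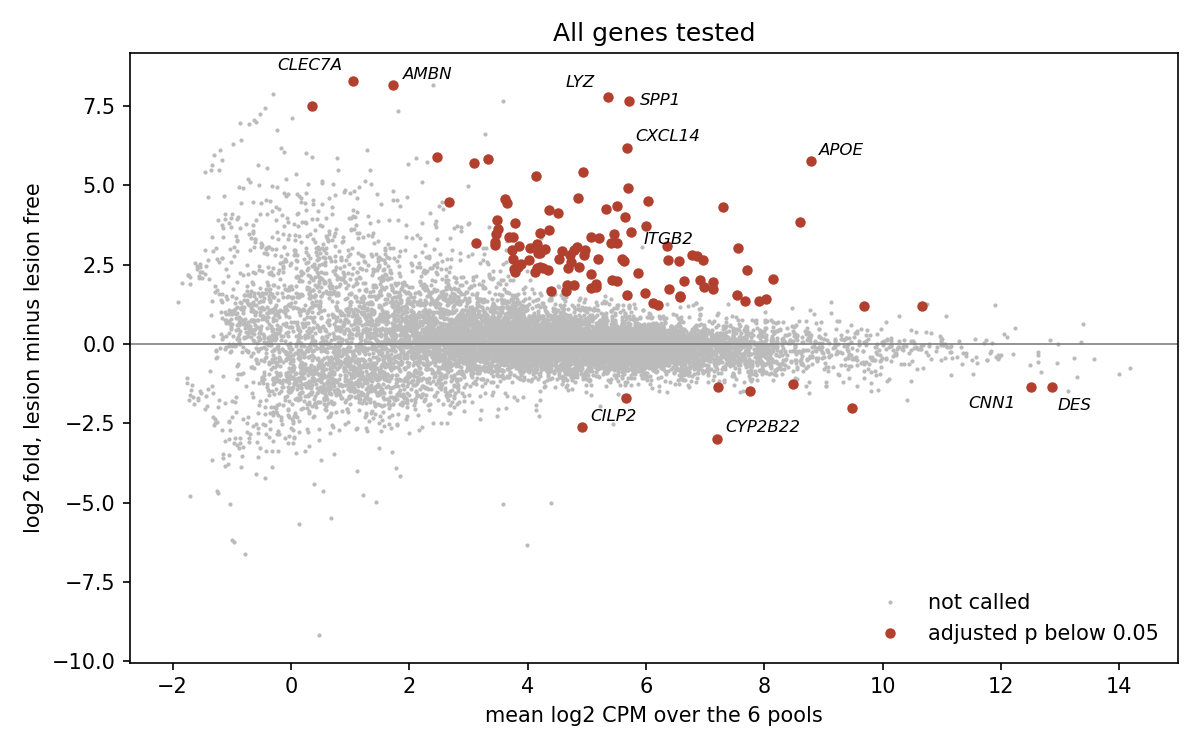
Log2 fold (lesion minus lesion free) against mean log2 CPM over the 6 pools for the 11673 genes tested, each point a gene, with called genes in red. Most red points lie above 0 (113 higher, 9 lower).

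Among called genes with a mean log2 CPM of at least 1, the 8 largest rises were in CLEC7A, AMBN, LYZ, SPP1, CXCL14, ADAM28, PLXNC1 and APOE. SPP1, the secreted phosphoprotein osteopontin, stood at 954 ± 838 CPM in lesion pools against 4.15 ± 2.35 CPM, and LYZ, lysozyme, at 749.6 ± 481 against 3.05 ± 1.75 CPM (SD, n = 3 each). CXCL14, a chemokine, rose 73.1-fold (limma adjusted p = 2.52e-05). CLEC7A, the myeloid receptor for beta-glucan, had 998 counts in the lesion pools together and 4 in the lesion-free pools, and AMBN, the enamel matrix protein ameloblastin, had 1528 and 6. With so few lesion-free counts their fitted log2 folds of 8.30 and 8.15 depend on the added count of 0.5. ADAM28, a metalloprotease, stood at 43.6 ± 5.14 against 1.10 ± 1.23 CPM, and PLXNC1, a semaphorin receptor, at 82.7 ± 30.6 against 2.33 ± 2.13 CPM. Of these genes, CXCL14 and APOE were called whichever pool was left out. The call was lost without lesion-free replicate 4 or 6 for SPP1 (adjusted p up to 0.162) and PLXNC1 (up to 0.104), and without any 1 of the 3 lesion-free pools for ADAM28 (up to 0.139), AMBN (up to 0.129), CLEC7A (up to 0.287) and LYZ (up to 0.493). AMBN also lost it without lesion replicate 1, and CLEC7A and LYZ without lesion replicate 1 or 3.

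The 8 named falls were the lower genes with a symbol, CYP2B22, CILP2, ACTA1, RBPMS, CNN1, DES, DNAJB5 and RBPMS2. CYP2B22, a cytochrome P450, was 7.90-fold lower, at 56.3 ± 21.8 CPM in lesion pools against 425 ± 159.9 CPM (SD, n = 3 each, limma adjusted p = 0.000414). CILP2, a cartilage matrix protein, was 6.17-fold lower, at 14.0 ± 11.2 against 79.2 ± 11.7 CPM (limma adjusted p = 0.0074). DES, the muscle filament protein desmin, stood at 4799 ± 1358 against 11779 ± 438 CPM, and ACTA1, skeletal alpha-actin, at 28.6 ± 7.96 against 94.2 ± 23.4 CPM. RBPMS and RBPMS2, which are RNA-binding proteins, and DNAJB5, a heat shock protein 40 relative, had log2 folds of -1.48, -1.26 and -1.34. CYP2B22 and CILP2 were called whichever pool was left out. RBPMS, CNN1, DES, DNAJB5 and RBPMS2 lost the call without lesion replicate 1 or lesion-free replicate 5 or 6 (adjusted p up to 0.159, 0.185, 0.278, 0.185 and 0.203). RBPMS2 also lost it without lesion replicate 2, and ACTA1 without lesion replicate 2 or lesion-free replicate 6 (up to 0.0952).

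**Figure D2:**
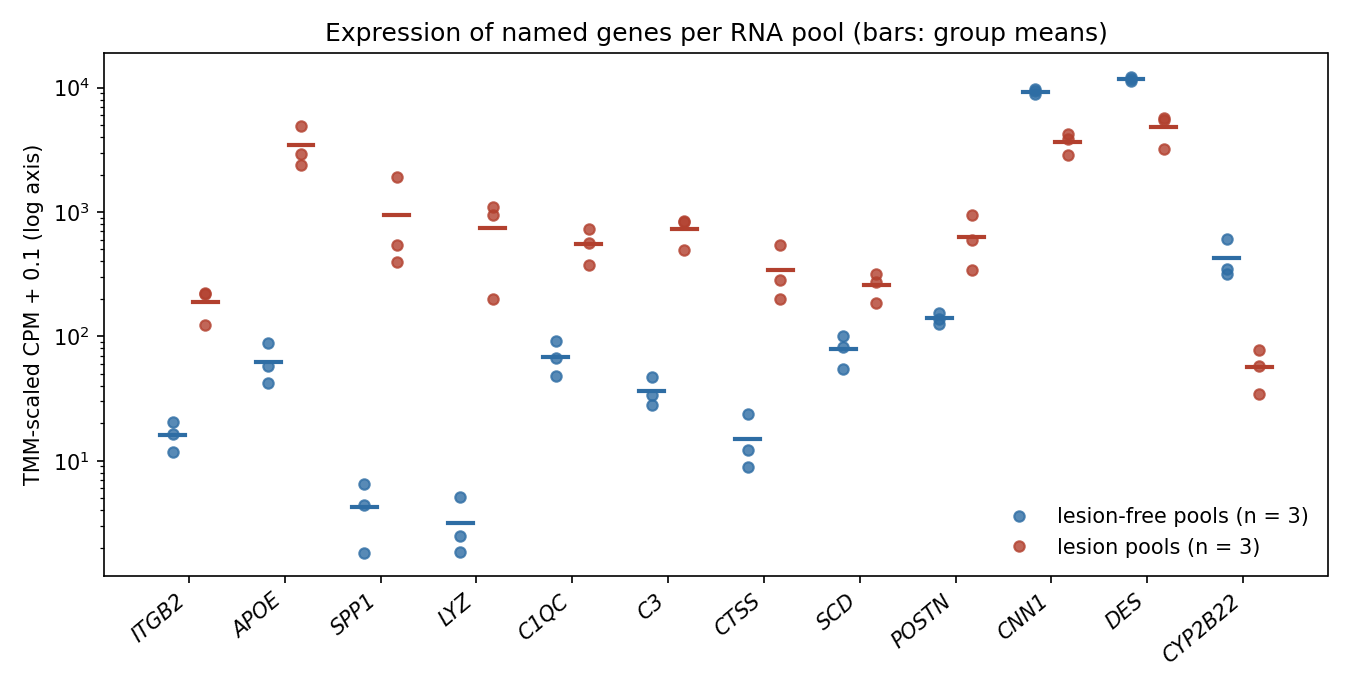
TMM-scaled CPM of 12 named genes in each of the 6 RNA pools, with 0.1 added for the log axis, points for single pools and bars for group means. Lesion pools lie above all lesion-free pools for ITGB2 through POSTN and below them for CNN1, DES and CYP2B22.

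Genes of leukocytes and macrophages were among those that rose. Of 28 tested leukocyte integrin and adaptor genes, 11 rose and 0 fell, or 25 and 0 when adjusted over the list alone, with a median log2 fold of 2.87. This list includes ITGB2, which the study singled out from these samples, so that gene's direction is not independent evidence. LCP1, the leukocyte actin-bundling protein L-plastin, rose 19.3-fold, and FCER1G, the signalling chain of Fc receptors, rose 13.1-fold. Of 21 macrophage and monocyte markers, 10 rose and 0 fell, or 14 and 0 when adjusted over the list alone. MSR1, a scavenger receptor for modified lipoprotein, rose 24.3-fold, MPEG1, a macrophage pore-forming protein, rose 8.47-fold, and C1QC, a chain of complement C1q, rose 8.13-fold. Without lesion-free replicate 6, 7 leukocyte genes were higher. Camera's adjusted p was 4.82e-30 for the leukocyte list and 2.58e-19 for the macrophage list. With an estimated correlation the adjusted p was 0.107 and 0.145, and neither call held. Camera's p-values here and below thus depend on the assumed correlation. Fry called both lists higher (fry adjusted p = 0.0165 and 0.0173).

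Some lipid-handling and lysosomal genes were called higher as well. Of 19 foam cell genes, 8 rose and 0 fell, or 15 and 0 when adjusted over the list alone, among them LGALS3, the galectin of activated macrophages, at 20.3-fold. ABCA1, the cholesterol exporter, rose 6.16-fold, and its symbol is carried by a further gene entry, which was also higher. Of 12 LXR target genes, which answer to the oxysterol-sensing nuclear receptors, 3 rose and 0 fell, or 5 and 0 when adjusted over the list alone. These were APOE, ABCA1 and SCD, a fatty acid desaturase that rose 3.30-fold. APOE and ABCA1 are also on the foam cell list. SREBF1, an uncalled member named outside the rule, was matched only through the synonym ADD1, a symbol another gene can carry. That match is uncertain, and it enters the results of the LXR list. Of 28 phagocyte oxidase and lysosome genes, 8 rose and 0 fell, or 15 and 0 when adjusted over the list alone. CTSS, a protease of antigen processing, rose 22.9-fold, CYBB, a subunit of the phagocyte oxidase, 18.9-fold, and CTSH, another lysosomal protease, 5.04-fold. The called genes LIPA and CTSB, named outside the rule, are also on the foam cell list, and CYBB is also on the macrophage list. The higher foam cell genes numbered 5 without lesion-free replicate 4 or 5 and 4 without 6, the higher lysosome genes 4 without 5 and 5 without 6, and the higher LXR targets 5 without lesion replicate 2. Camera's adjusted p was 1.77e-20, 3.77e-07 and 3.56e-19 for the foam cell, LXR and lysosome lists. With an estimated correlation the adjusted p was 0.107 for each of them, and none of these calls held.

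Most antigen presentation genes tested and some complement genes were also called higher. Some of these were counted above already. The called genes C1QC and C1QA, the latter named outside the rule, are on the complement and macrophage lists. CTSS is on the class II and lysosome lists. Of 9 genes of MHC class II presentation, 7 rose and 0 fell, or 8 and 0 when adjusted over the list alone, including SLA-DMB, a peptide loader, at 6.43-fold and IFI30, a lysosomal thiol reductase, at 6.36-fold. The number of higher genes on this list was 4 without lesion replicate 1 and 3 without lesion-free replicate 5 or 6. Of 16 complement genes, 5 rose and 0 fell, or 6 and 0 when adjusted over the list alone. C3, the central complement component, rose 19.99-fold, from 36.3 ± 9.96 to 723 ± 195 CPM (SD, n = 3 each), and C5AR1, the receptor of the C5a fragment, rose 11.0-fold. Camera's adjusted p was 8.01e-15 for the class II list and 3.77e-07 for complement, against an adjusted p of 0.107 and 0.186 with an estimated correlation.

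In the other immune lists few or no single genes were called. Of 17 innate sensing and cytokine genes, 1 rose (CLEC7A), or 5 when adjusted over the list alone, and 0 rose without any 1 pool other than lesion replicate 2. Of 17 chemokine and receptor genes, 1 rose (CXCL14), or 6 higher and 2 lower when adjusted over the list alone, and 2 rose without lesion replicate 2. Of 5 dendritic cell markers, 1 rose, WDFY4, a protein of cross-presentation, 12.3-fold, or 3 when adjusted over the list alone. Of 8 endothelial activation and adhesion genes, 1 rose, SELPLG, the leukocyte ligand of P-selectin, 23.7-fold, or 4 when adjusted over the list alone, and 2 rose without lesion replicate 1 or 3. WDFY4 lost its call without any 1 of the lesion-free pools (adjusted p up to 0.0883) and SELPLG without lesion-free replicate 6 (adjusted p = 0.0608). Camera called these 4 lists higher (adjusted p from 2.7e-05 to 0.00244), and with an estimated correlation the adjusted p was 0.186, 0.294, 0.199 and 0.162. None of 23 interferon response genes was called, nor any of 8 T cell markers. Camera called the interferon list higher (adjusted p = 0.000879) but not without lesion replicate 3 (adjusted p = 0.0934) or with an estimated correlation (adjusted p = 0.351). The T cell list was not called (adjusted p = 0.209) except without lesion replicate 1 (adjusted p = 0.0368). Medians were 1.31 over 3 B and plasma cell markers and 3.98 over 2 cytotoxic genes. None of these was called, except 1 cytotoxic gene when adjusted over the list alone or without lesion replicate 2.

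Few contractile smooth muscle genes were called, and those were lower. Of 22 tested markers, 0 rose and 2 fell (CNN1 and DES), or 0 and 9 when adjusted over the list alone, with a median log2 fold of -0.59. Without lesion replicate 1 or lesion-free replicate 5 or 6, 0 fell. The list median was -0.56, -0.57 and -0.58 in lesion replicates 1, 2 and 3, relative to the lesion-free mean. Camera called this list lower (adjusted p = 1.37e-06), and with an estimated correlation the adjusted p was 0.199. Fry did not call it (fry adjusted p = 0.0647). Of 29 fibrillar collagen and matrix assembly genes, 2 rose and 0 fell, or 3 and 0 when adjusted over the list alone. These were POSTN, the matricellular protein periostin, at 4.18-fold and VCAN, the proteoglycan versican, at 3.91-fold, of which VCAN was not called without lesion replicate 1 (adjusted p = 0.0697). Camera called this list higher (adjusted p = 0.00244) but not without lesion-free replicate 4 (adjusted p = 0.0875) or with an estimated correlation (adjusted p = 0.429). Of 7 osteogenic genes, 1 rose (SPP1), or 3 when adjusted over the list alone, with a median of 0.12 and camera's adjusted p = 0.0261. SPP1, which is also on the foam cell list, was the only one called, and 0 were without lesion-free replicate 4 or 6. The osteogenic list's call was lost without lesion-free replicate 6 (adjusted p = 0.0891) and with an estimated correlation (adjusted p = 0.199). No gene was called among modulated smooth muscle, elastic fibre, matrix protease, TGF-beta or oxidative phosphorylation genes. Their medians were -0.09 over 10 genes, -0.34 over 13, 0.31 over 18, 0.04 over 19 and -0.08 over 30, and camera called none of these lists, except oxidative phosphorylation as lower without lesion replicate 1 (adjusted p = 0.00288) or lesion-free replicate 5 (0.0449) or 6 (0.00337). With p adjusted over the list alone, 1 modulated smooth muscle gene was higher and 1 lower, and 3 protease genes were higher. Without lesion replicate 2, 2 protease genes were higher and 1 modulated gene was lower, and without lesion replicate 1 or 3, 1 modulated gene was higher.

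**Figure D3:**
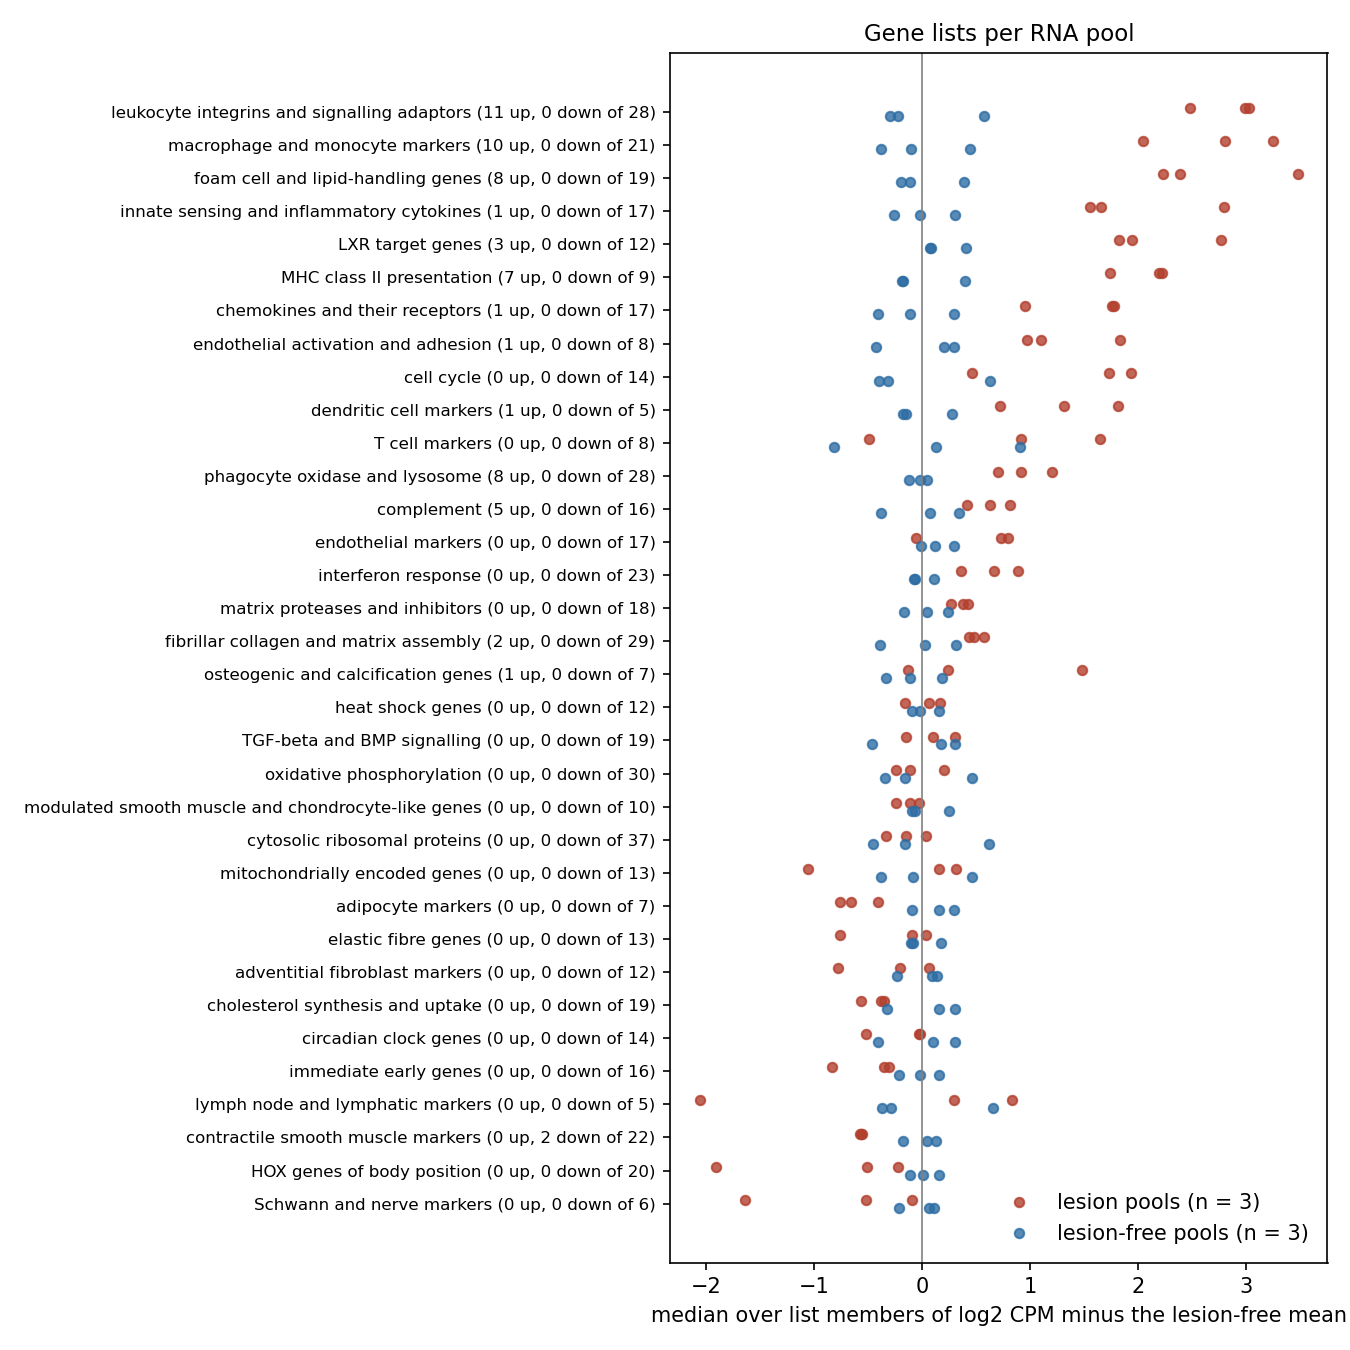
Median log2 CPM of the members of each of the 34 tested lists, relative to the lesion-free mean of each gene, with 1 point per pool and, after each list name, the members called higher and lower of those tested. All lesion pools lie above all lesion-free pools for the leukocyte, macrophage and foam cell lists and below them for the contractile list. Some other lists also separate, upward as for matrix proteases and downward as for the HOX, immediate early, adipocyte and cholesterol lists.

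No cholesterol synthesis or cell cycle gene was called. Of 19 cholesterol synthesis and uptake genes 0 were called, or 1 higher when adjusted over the list alone, with a median of -0.38, and of 14 cell cycle genes 0 were called with a median of 1.25. Camera called the cholesterol list lower (adjusted p = 0.0261) and the cell cycle list higher (adjusted p = 0.003), and with an estimated correlation the adjusted p was 0.385 and 0.429. The cholesterol call was lost without lesion replicate 2 (adjusted p = 0.137) or 3 (0.134) or lesion-free replicate 4 (0.1305) or 6 (0.0895), and 1 cholesterol gene was higher without lesion replicate 2. Among lists of other cell types, 0 of 17 endothelial, 0 of 12 adventitial fibroblast, 0 of 7 adipocyte, 0 of 6 nerve and 0 of 5 lymphatic markers were called, with medians of 0.57, -0.37, -0.32, -0.71 and -0.57. In each of these lists lesion replicate 1 had the lowest median of the lesion pools. Relative to the lesion-free mean, the lymphatic median was -2.06, 0.29 and 0.83 in lesion replicates 1, 2 and 3. The nerve median was -1.65, -0.52 and -0.10. Camera called the endothelial list higher (adjusted p = 0.0261), and with an estimated correlation the adjusted p was 0.351. That call was lost without lesion replicate 2 (adjusted p = 0.117) or 3 (0.163) or lesion-free replicate 6 (0.0547), and the adventitial list was called lower without lesion-free replicate 6 (0.0465). With p adjusted over the list alone, 1 lymphatic marker was higher and 1 lower. Medians were 0.05 over 3 skeletal muscle genes, of which ACTA1 fell, and 0.88 over 4 mast cell markers. They were 0.33 over 2 red blood cell genes, 0.61 for 1 mesothelial gene and -1.19 over 2 sex-linked genes. Relative to the lesion-free mean, the sex-linked median was 0.06, 0.85 and -3.65 in lesion replicates 1, 2 and 3. In lesion-free replicates 4, 5 and 6 it was 0.98, -2.77 and 1.79. Whether the pools differed in sex was not tested. The single neutrophil marker tested was MMP9, named outside the rule and also on the matrix protease list. Its log2 fold was 7.66, and it was called without lesion replicate 2. It also passed when adjusted over the neutrophil list alone, but with 1 tested member that leaves p unadjusted. The others of the 11 matched neutrophil markers had counts too low to be tested.

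Lists of handling and body position held no called gene, apart from 1 lower heat shock gene when adjusted over the list alone or without lesion replicate 3. Of the immediate early genes, 1 was lower without lesion replicate 3 and 2 without lesion-free replicate 4. Camera called 16 immediate early genes lower (median -0.44, adjusted p = 0.00742), and likewise 20 HOX genes of body position (median -0.69, adjusted p = 0.0156). With an estimated correlation the adjusted p was 0.326 and 0.429. The HOX call was lost without lesion-free replicate 4 (adjusted p = 0.073). Lesion replicate 1 stood apart in the HOX genes, with a median of -1.91 relative to the lesion-free mean against -0.22 and -0.51 in the other lesion pools. Medians were 0.09 over 12 heat shock, -0.39 over 14 circadian, -0.15 over 13 mitochondrially encoded and -0.14 over 37 ribosomal protein genes, and camera called none of these lists with all pools. Without single pools, camera called the mitochondrial list lower without lesion replicate 1 (adjusted p = 0.00545) or 3 (0.0057) or lesion-free replicate 6 (0.0141). It called the ribosomal list lower without lesion replicate 1 (0.0171) or 3 (0.0112) or lesion-free replicate 5 (0.0166) or 6 (1.35e-05), and higher without lesion-free replicate 4 (0.0453).

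Few isoforms were called, most of them higher in lesion pools. Of 12666 isoforms tested with limma, 53 were higher and 4 lower in lesion pools. Of these 57 isoforms, 37 could be tied to a called gene, and all 37 took that gene's direction, which their share in the gene's counts largely fixes. Among uncalled isoforms of genes that rose, MSR1-002, SCD-004 and VCAN-202 had log2 folds of -1.31, -0.69 and -1.22 (SE 2.67, 1.48 and 2.53). ITGB2 had 1 tested isoform with a log2 fold of 3.54 (SE 0.39, limma adjusted p = 0.00299). Of the POSTN isoforms, POSTN-202 rose with a log2 fold of 2.49 (SE 0.37, limma adjusted p = 0.0181), and POSTN-201 had a log2 fold of 0.77 (SE 0.40, adjusted p = 0.622). The number of higher isoforms was 32 without lesion replicate 3, 25 without lesion-free replicate 4, 16 without replicate 5 and 17 without replicate 6. The number of lower isoforms was 1 without lesion replicate 1 or lesion-free replicate 5, and 2 without lesion-free replicate 4 or 6.

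Unequal change of the isoforms of a gene was not detected. Of 611 genes tested with limma's diffSplice, 0 passed by the Simes or the F test, and 32 had an unadjusted Simes p under 0.05. Among the genes with the smallest p, the adjusted p was 0.131 for CCDC66 and PSAP, 0.201 for TLR4 and 0.506 for MRC2. PSAP, the precursor of the saposins that aid lysosomal lipid breakdown, is an example. Its isoform PSAP-201 stood at 2498, 1264 and 1942 CPM in the lesion pools and at 289, 446 and 335 CPM in the lesion-free pools, and PSAP-202 at 254, 872 and 556 against 787, 536 and 824 CPM. MRC2, a collagen receptor, had MRC2-002 at 10.5, 9.96 and 4.596 CPM in lesion pools and 79.5, 31.4 and 19.1 CPM in lesion-free pools. CCDC66 and TLR4, the endotoxin receptor, each had an isoform at 0 counts in the 3 lesion pools and above 0 in the 3 lesion-free pools.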

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

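The limma-trend, thinned and protein-coding fits, and quality weights for the lists, were chosen after seeing the data; the other alternatives were planned. The planned DESeq2 fits, the edgeR exact test and the GC correction were not run, the first because count models were set aside and the last for want of a reference genome. No paired analysis was possible because the groups share no replicate numbers. The filter of 1 CPM in 3 pools kept exactly the genes of the main filter and tests nothing. Library totals without scaling moved the median gene by 0.167 on the log2 scale. Every one of the 113 higher and 9 lower genes that was tested in an alternative kept its sign there. Higher and lower genes numbered 171 and 17 without a low-count filter, where more genes were tested, and 213 and 40 with sample quality weights, and the cause was not tested. With 1 pool left out, where fewer samples were used, they numbered 55 to 150 and 4 to 36. With every pool thinned to the smallest total, 78 higher and 6 lower genes remained of the 113 and 9, so the number of calls fell with depth. Of 36 called named genes, 21 were called in all alternatives, 15 lost the call in at least 1, 6 of these with a pool left out only, and 0 reversed. LYZ was also lost with each other scaling tried and with quality weights, at log2 folds of 7.32 to 8.55 over all alternatives. Lists numbered 16 higher and 4 lower with camera's preset correlation, 0 and 0 with an estimated correlation, and 10 and 0 with fry. The 10 were the leukocyte, macrophage, foam cell, lysosome, LXR, class II, complement, innate sensing, dendritic cell and endothelial adhesion lists. Their fry adjusted p ran from 0.0061 to 0.0392. Fry did not call the contractile (0.0647), chemokine (0.110), fibrillar collagen (0.264) or osteogenic (0.0578) lists. With 1 pool left out, camera with the preset correlation called 14 to 17 lists higher and 2 to 7 lower. Higher and lower isoforms numbered 101 and 16 without a filter, and 16 to 62 and 1 to 3 with 1 pool left out. Isoform use gave 0 genes in every alternative run.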

Other observations

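The tests of the first and second patterns below were chosen after the results they measure had been seen in other form. The isoform count of the third was chosen after single such isoforms were seen but before they were counted. The genes named in the next 2 paragraphs were chosen after their values were seen.

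Of the 113 genes higher in lesion pools, 63 were on none of the fixed lists. S100A4, a calcium-binding protein of motile cells, had a log2 fold of 4.92 (SE 0.43), at 297 CPM in lesion pools against 9.60 CPM. RNF128, a ubiquitin ligase, stood at 235 ± 171 against 4.85 ± 1.76 CPM (SD, n = 3 each), with 432, 129 and 144 CPM in lesion replicates 1, 2 and 3. HAVCR2, the immune checkpoint receptor TIM-3, stood at 63.4 ± 15.4 against 1.12 ± 0.18 CPM. The log2 fold was 2.65 for GM2A, the GM2 ganglioside activator, 2.24 for ASAH1, acid ceramidase, and 1.55 for SGPL1, sphingosine phosphate lyase. GIMAP1, GIMAP4 and GIMAP6, small GTPases of immune cells, had log2 folds of 2.67, 3.12 and 2.34. P2Y12R, the ADP receptor of platelets and some macrophages, had a mean of 17.4 CPM in lesion pools against 0.0678 CPM. These groups were not tested for enrichment.

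Among uncalled genes, INSIG1, which holds back cholesterol synthesis, had a log2 fold of 1.83 (SE 0.44, limma adjusted p = 0.0691), against the list median of -0.38. MMP9, the gelatinase and the single neutrophil marker tested above, had a mean of 205 CPM in lesion pools against 2.01 CPM (limma adjusted p = 0.151). In lesion replicate 3, immunoglobulin genes held 852 CPM of the library total without TMM scaling, against 29.2 and 35.1 in the other lesion pools and 72.2 to 168 in the lesion-free pools. The same pool held 4242 CPM of the class of small structured RNAs that includes 7SK and the signal recognition particle RNA, against 120 to 660 in the other 5 pools. Of 4 other RNA classes, 3 separated the groups. In lesion replicates 1, 2 and 3 ribosomal RNA genes held 134, 43.2 and 56.0 CPM against 11.8, 4.00 and 22.6 in the lesion-free pools, and small nuclear RNA 26.0, 9.65 and 43.4 against 6.10, 7.77 and 7.98. Small nucleolar RNA held 12.5, 7.46 and 26.2 against 5.45, 1.77 and 5.86. Mitochondrial ribosomal RNA did not separate them, at 2529, 822 and 2026 against 1369, 1269.8 and 1068.5 CPM. RNA quality or library making that differed between the groups was not tested, and these classes were looked at after the data were seen.

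The first pattern weighed was the rise of leukocyte genes. Unequal depth may not account for it, since the leukocyte list had a median log2 fold of 2.87 in the full data and 2.98 with every pool thinned to the smallest total. Nor did pool 1 carry it alone, since the median was 2.69 without that pool. A smaller share of smooth muscle would raise all other cell types alike, yet the macrophage median exceeded the endothelial median by 2.36 more in lesion than in lesion-free pools on the log2 scale, where the SD between pools was 1.01 and 0.505. That excess is not what a smaller muscle share alone would give. Only the endothelial list was compared, so a smaller muscle share may still make up part of the rise. A larger share of macrophages, a change within macrophages, RNA quality or library making that differed between the groups, the swine line and the lesion itself stay open, since these pools hold lesion and line together. So do sex, age, diet and sequencing batch, which the labels do not give per pool.

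The second pattern was the distance of pool 1 (lesion replicate 1) from the other pools, of which lower depth was a candidate explanation. Of 7502 genes with a mean of at least 10 CPM, 54 had no count in pool 1. After pools 2 and 3 were thinned to its total, 5 and 8 of these genes had no count in them. The correlation across genes of thinned pools 2 and 3 exceeded that of either with pool 1 by 0.082, so lower depth alone did not account for the distance. Of all 11673 genes tested, 973 had no count in pool 1 and a count in every other pool, before any thinning. How far these missing counts lowered the list medians of pool 1 was not tested. Fewer distinct RNA molecules in that library and differing animals in the pool remain untested.

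The third pattern was isoforms absent from 1 group and present in the other, as in CCDC66 and TLR4. In 5 genes an isoform made up at least 0.2 of the gene's counts in all pools of 1 group and at most 0.01 in the other group. Of the other 9 splits of the 6 pools, the highest gave 15 such genes. The 5 switches are consistent with counts that move as a whole between isoforms from pool to pool, whatever the group. A sequence difference between the swine lines was not tested.

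With 6 pools there are 10 splits into 3 and 3, too few for a share under 0.05. For genes, 1 split of 10, the real one, gave as many as 122 calls, and the highest other gave 0. For isoforms, 1 split of 10 gave as many as 57 calls, and the highest other gave 0. For lists tested with camera at the preset correlation, 1 split of 10 gave as many as 20 calls, and the highest other, pools 1, 3 and 4 against the rest, gave 17, with 3 to 15 in the remaining 8. For isoform use, all 10 splits gave at least the real count of 0, and the highest other gave 1. Each mixed split sets 2 pools of a group and 1 of the other against the reverse and so holds part of any real difference, which keeps these counts from being counts without a difference. The interferon, cholesterol, cell cycle, endothelial, immediate early and HOX lists held no called member and were not called with an estimated correlation or by fry.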
